A study of Homo sapiens with 10 samples.

How the data were processed

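The samples were human monocyte-derived macrophages (hMDMs, macrophages grown in culture from blood monocytes) treated with interferon gamma for 18 h. METTL3 encodes the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on messenger RNA. The groups were 5 libraries labelled METTL3 knockout and 5 control libraries, taken from the titles and cell type labels. The titles of the control libraries carry NTC, taken here to mean a non-targeting control. Per the labels' protocols, RNA was isolated with a Qiagen RNeasy kit, libraries were made with the Illumina kit for stranded mRNA, and single-end reads came from a NovaSeq instrument. The series title also names a METTL14 knockout, which was not analysed here. No unstimulated library was analysed here, so the response to interferon gamma itself was not measured.

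The authors deposited for each library a table of 20320 protein-coding genes by Ensembl identifier with a raw read count, a gene width and an RPKM, per the file headers. Per the submitters' processing notes, reads were aligned with GSNAP to hg38. The version of the aligner, the counting tool, its strand setting and the annotation were not given in the sources used here. Counts on overlapping genes on opposite strands may therefore be mixed, and genes that share reads with close copies are uncertain. The deposited RPKM values are the counts divided by the width and by a per-library total, recovered from the files, of 29171221 to 30674488. What that total counts was not given in the sources used here. The summed counts were 52.7 ± 0.527% of that total in the knockout libraries and 51.8 ± 0.986% in the control libraries (mean ± SD, n = 5 each). The widths were the same in all 10 files, and 77.6% were multiples of 3. Of the widths, 82.8% were within 5% of the summed coding exons of GENCODE v29, against 3.0% for all exons, so the width is a coding length and reads on untranslated regions appear not to be counted. The RPKM values were used only to recover that total.

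Gene symbols came from a table of Ensembl identifiers and symbols, which held 20181 of the 20320 identifiers. GENCODE v29 (GRCh38) held 20288 and 32 were in neither. Of the identifiers, 12 shared a symbol with another, and the identifier was then added to the symbol. Coordinates and exon structures are those of GENCODE v29, 1-based.

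Total counts ran from 15362479 to 15944942 per library, so 1 CPM (a count per 1e6 counts of the library) was 15.4 to 15.9 reads. Between 13154 and 13706 genes had a count in a library. Mitochondrially encoded genes took 5.75 ± 0.507% of counts in knockout and 5.48 ± 0.251% in control libraries, and the 10 most abundant genes 11.1 ± 0.408% and 11.0 ± 0.614% (mean ± SD, n = 5 each). Reads carried no molecular identifiers, so read numbers give counting error only and are not numbers of molecules.

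Raw counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM (factors 0.954 to 1.056), and tested with the version 4 quasi-likelihood F test with robust dispersions and donor as a block, which leaves 4 residual degrees of freedom per gene. P values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are log2 of knockout over control with their standard error (SE, the log2 fold change divided by the square root of F). Mean CPM values are TMM-scaled and given ± SD over 5 libraries. Ratios within a donor use log2 CPM with a prior count of 2.

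Donor was in the main model because the series' design text places the perturbation within each of 5 donors. The replicate number of the titles was taken as the donor. As a check, deviations of same-numbered libraries from their group means correlated at 0.744, 0.870, 0.647, 0.737 and 0.782 across genes, against at most 0.069 for differently numbered libraries. The fit without the block was an alternative. In the check for mixed-up samples on sex-linked genes, 0 donor pairs disagreed. The reads of every library pair differed by more than sampling noise (lowest chi-square per degree of freedom 22.4), so no library was a duplicate.

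The choice of test, model, gene lists, named genes and alternatives was made before the data were examined, except where stated. Of 43 gene lists, written from general knowledge and none chosen on these samples, 37 with at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) against the other genes, with Benjamini-Hochberg over the 37. Camera with an estimated correlation and fry, which asks whether a list's own genes move on balance in a direction, were alternatives. CARD17 and the alias TTP were not matched to a single gene and were left out. ZFP36, which TTP was meant to name, stood in the same list under its own symbol. Genes were named by a rule. It took 12 genes set in advance, the 8 largest changes in each direction, and up to 3 members of each core list or 1 of each further list by absolute log2 fold change. Except for the 12, these needed adjusted p under 0.05, a mean of at least 5 CPM and the same direction in all 5 donors. The values of some genes are not reported here. Genes on chromosome Y, XIST and genes with common whole-gene deletions were left out. A core list without such a member and each cell type list named the member of highest mean CPM. Other genes named in the text were chosen after their values were seen, which holds for members of lists given by symbol only and for those named with values as such.

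The alternatives were no replicate block, DESeq2 size factors, upper-quartile scaling, total counts, no filter, a filter of at least 1 CPM in 5 libraries, the DESeq2 1.42.0 Wald test, limma-voom, non-robust dispersions, the older edgeR test, a test against a fold of 1.2 (glmTreat), 1 surrogate variable (sva 3.50.0) in place of the block, and leaving out both libraries of each donor in turn. A correction for GC content and coding length with the replicate block was added after seeing the data. Counts were also simulated with the real means, library sizes and dispersions, with 11209 genes run. At each fold 50 genes were changed, taken only from those with a mean of at least 5 CPM. The test recovered 26.0% at a fold of 1.2, 98.0% at 1.5 and 100.0% at 2 and at 3. Of 174 genes called there, 12 were unchanged. With only 200 genes changed in all, recovery at small folds may differ from that in the real counts. Relations across genes, random lists and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.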

Results

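RNA was measured in macrophages from 5 donors, each giving a METTL3 knockout library and a control library, all after 18 h of interferon gamma. The question put by the design was how loss of METTL3 changes the transcriptome of interferon-stimulated human macrophages. Total counts were 15362479 to 15753981 in the 5 knockout libraries and 15388873 to 15944942 in the 5 control libraries. Replicates were separate donors, and 11282 genes passed the count filter.

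METTL3 itself (ENSG00000165819, chromosome 14, 21498133 to 21511375, minus strand, hg38) fell from 51.8 ± 4.35 CPM in control to 12.9 ± 2.04 CPM in knockout libraries (SD, n = 5 each). The log2 fold change was -2.02 ± 0.10 (SE; edgeR adjusted p = 5.3e-09, lower in 5 of 5 donors), a 4.04-fold lower level. Transcripts of an edited gene can still be sequenced, so the remaining counts do not measure the share of unedited cells. The annotated 3' end of METTL3 overlaps TOX4 on the opposite strand, for which the log2 fold change was -0.04 ± 0.06 (adjusted p = 0.680). Some other subunits of the methyltransferase complex were higher. WTAP, the regulatory subunit, rose from 36.8 ± 5.72 to 102 ± 12.9 CPM (log2 fold change 1.48 ± 0.07, adjusted p = 5.3e-09, higher in 5 of 5 donors). RBM15, an RNA-binding adaptor of the complex, rose from 20.9 ± 1.86 to 42.3 ± 3.21 CPM (1.02 ± 0.08, adjusted p = 1.08e-06). METTL14, the partner that forms a heterodimer with METTL3, did not pass the test, at 24.3 ± 2.28 and 28.4 ± 5.14 CPM (0.21 ± 0.09, adjusted p = 0.0853, higher in 4 of 5 donors). It passed without replicate 4 (adjusted p = 0.0268) and with the GC content and length correction (0.0152). Among 26 tested members of the m6A machinery list, 10 rose, 2 fell and 14 did not pass, or 11 higher and 4 lower adjusted over the list alone. Besides WTAP and RBM15, the risers were VIRMA, ALKBH5, YTHDF1, METTL16, YTHDC1, CBLL1, RBM15B and YTHDF2, and besides METTL3, YTHDC2 fell. The list ranked higher than other genes (camera adjusted p = 0.0379), but adjusted p = 0.743 with an estimated correlation and 0.119 without replicate 1. Fry, which asks whether a list's own genes move on balance in a direction, gave adjusted p = 0.0372.

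**Figure D1:**
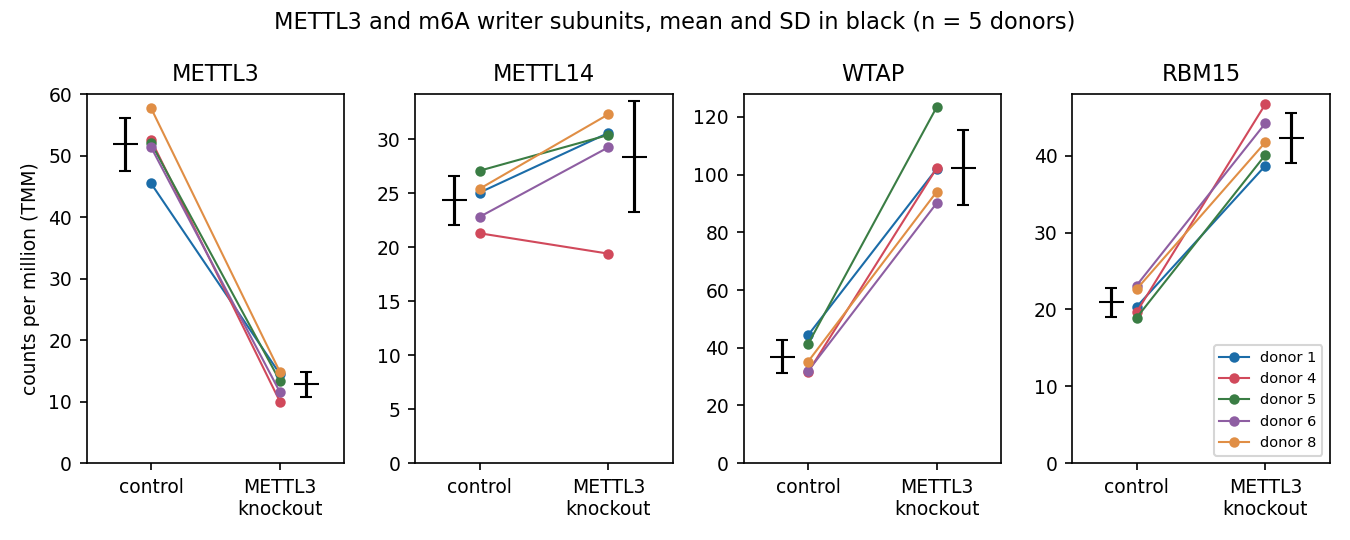
CPM (y axis, TMM-scaled, from 0) of METTL3, METTL14, WTAP and RBM15 in control and METTL3 knockout macrophages, where points joined by a line are the libraries of a donor and black marks are means ± SD (n = 5). METTL3 is lower and WTAP and RBM15 are higher in the knockout library of all 5 donors, and METTL14 is higher in 4 of 5.

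Across all genes tested, 2873 (25.5%) passed the threshold, 1581 higher and 1292 lower in the knockout. Most changes were small, with a median absolute log2 fold change of 0.351 among them. The genes at least 2-fold higher numbered 111 and those at least 2-fold lower 44, while 1217 higher and 1115 lower genes differed by less than 1.5-fold. Of all genes tested, 32.4% moved the same way in all 5 donors, where chance gives 6.25%. The largest increases by the naming rule were those of CYP27B1, the enzyme that makes active vitamin D (58.3 ± 42.6 to 180 ± 131 CPM; log2 fold change 1.66 ± 0.08, adjusted p = 1.19e-08), of NPTX2 (1.64 ± 0.21) and of GP1BA, a platelet glycoprotein gene (1.55 ± 0.23). They were followed by WTAP, DNHD1 (1.48 ± 0.08), H2AJ, a histone variant (1.39 ± 0.16), PLEKHG3 (1.36 ± 0.15) and IL32, a cytokine gene (1.36 ± 0.16). After METTL3, the largest decreases by the naming rule, which asks for at least 5 CPM and the same direction in all 5 donors, were those of CD180, a toll-like receptor homologue (38.8 ± 35.5 to 12.6 ± 12.2 CPM; log2 fold change -1.63 ± 0.11, adjusted p = 2.17e-07), and SDS, serine dehydratase (-1.33 ± 0.21). FN1, fibronectin, fell as well (7053 ± 5881 to 3635 ± 4670 CPM; -1.30 ± 0.20, adjusted p = 0.00629), as did the transporter ABCG2 (-1.23 ± 0.13), SCIN, an actin-severing protein (-1.20 ± 0.11), RGS18 (-1.14 ± 0.17) and the scavenger receptor STAB1 (-1.09 ± 0.18). Levels differed widely between donors, whereas the test compares libraries within donors. Without the replicate block the same counts gave 10 calls, 9 higher and 1 lower, all of them among the 2873; 1 surrogate variable in its place gave 208. Without replicate 5 there were 1696 calls, and 538 genes passed a test against a fold of 1.2.

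**Figure D2:**
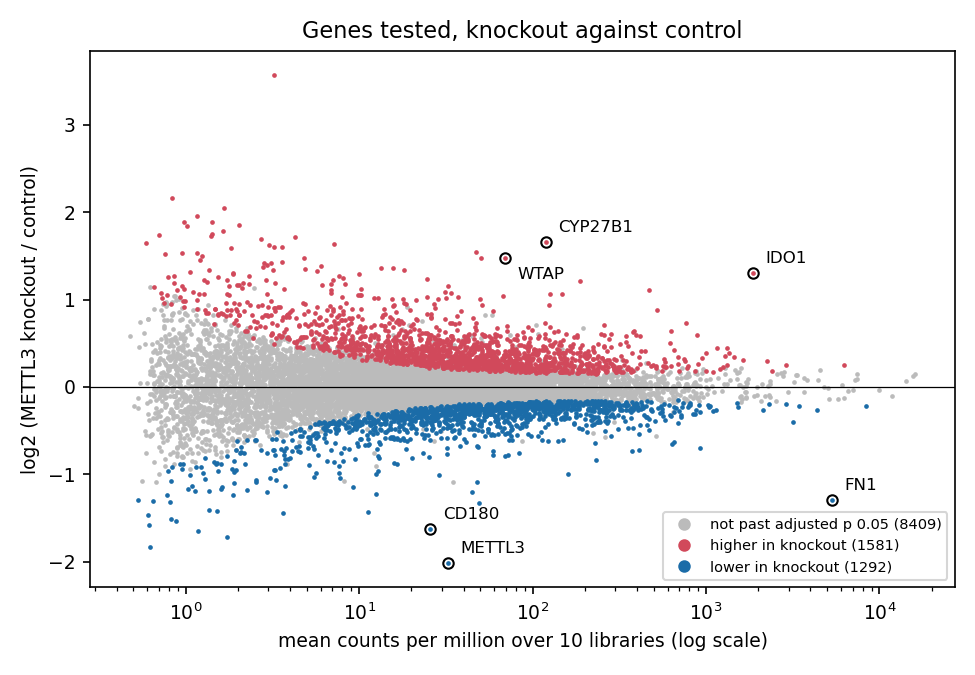
Each of the 11282 genes tested, by mean CPM over the 10 libraries (x axis, log scale) and log2 fold change of knockout over control (y axis). Red and blue points are the 1581 higher and 1292 lower genes at adjusted p under 0.05, most of them within 1.5-fold, and circles mark named genes.

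The established targets of interferon gamma did not move in a common direction. IDO1, which degrades tryptophan, rose from 1204 ± 1048 to 2540 ± 1977 CPM (log2 fold change 1.31 ± 0.25, adjusted p = 0.0188, higher in 5 of 5 donors). CIITA, the MHC class II transactivator, fell slightly (132 ± 51.3 to 116 ± 41.7 CPM; -0.17 ± 0.06, adjusted p = 0.0463, lower in 5 of 5 donors). The following did not pass. IRF1 stood at 389 ± 154 and 406 ± 177 CPM (0.01 ± 0.08, adjusted p = 0.909) and the GTPase gene GBP1 at 0.15 ± 0.11 (adjusted p = 0.355). The chemokines CXCL9 and CXCL10 were at 0.28 ± 0.18 (adjusted p = 0.340) and 0.20 ± 0.28 (adjusted p = 0.659). CD274, which encodes PD-L1, was at 0.44 ± 0.15 (adjusted p = 0.0725, higher in 4 of 5 donors) and HLA-DRA at -0.14 ± 0.08 (adjusted p = 0.234). Some calls ended with fewer donors while the fold stayed similar. IDO1 was lost without replicate 4, 5 or 6 (log2 fold changes 1.28, 1.25 and 1.36; adjusted p = 0.0715, 0.0732 and 0.0548). CIITA was lost without 4, 5, 6 or 8 (-0.14, -0.20, -0.15 and -0.17; adjusted p = 0.136, 0.0604, 0.126 and 0.0819) and with DESeq2 (0.0588). Other folds grew when a donor was left out. CXCL10 passed without replicate 4 (log2 fold change 0.43, adjusted p = 0.0166), CXCL9 without 6 (0.46, adjusted p = 0.00201), and CD274 and HLA-DRA without 8 (0.63, adjusted p = 2.9e-05, and -0.24, adjusted p = 0.0228). CD274 also passed with limma-voom (0.0137) and non-robust dispersions (0.0109). Several of these genes were low in the control library of replicate 4, with IDO1 at 12.6, GBP1 at 200, IRF1 at 161 and CD274 at 26.0 CPM. The other control libraries had 245 to 2253, 841 to 1961, 314 to 531 and 60.3 to 322 CPM. CXCL10 was lowest in the control library of replicate 4 as well, at 34.4 CPM (other control libraries 43.2 to 236). CXCL9, CIITA and HLA-DRA were lowest in the control library of another donor. Whether the donor of replicate 4 responded less to interferon gamma was not tested.

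**Figure D3:**
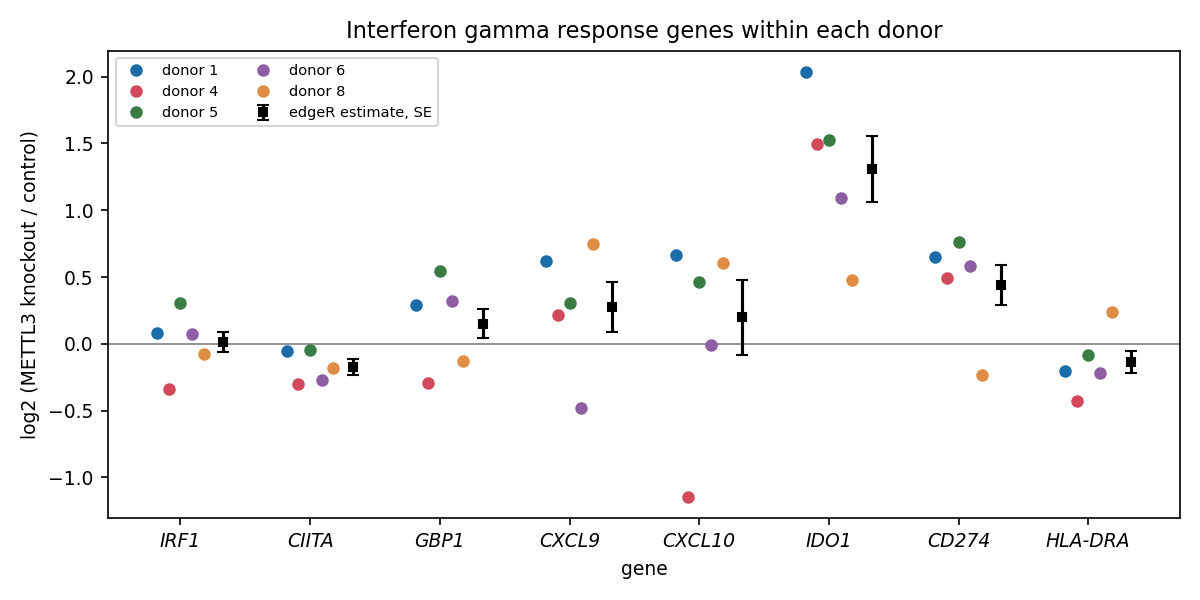
Log2 ratio of METTL3 knockout over control (y axis) for 8 interferon gamma response genes (x axis), with a coloured point per donor and the edgeR estimate ± SE in black. IDO1 lies above 0 and CIITA below 0 in all 5 donors, whereas the other genes have points on both sides.

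In the whole type II interferon response list, 13 of 64 tested members rose, 9 fell and 42 did not pass, or 18 higher and 11 lower adjusted over the list alone. The risers were led by IL32, IDO1 and the complement protease gene C1S (94.8 ± 27.8 to 202 ± 71.6 CPM; log2 fold change 1.07 ± 0.19, adjusted p = 0.0136; 0.0595 and 0.0627 without replicates 4 and 5). The list did not pass against other genes (camera adjusted p = 0.111), although it did without replicate 4, 6 or 8 (adjusted p = 0.00308, 0.0454 and 0.0039). Among type I interferon-stimulated genes, 15 of 55 rose, 3 fell (SAMHD1, SAMD9 and DDX60L) and 37 did not pass, or 16 higher and 4 lower adjusted over the list alone. ISG15, a ubiquitin-like modifier, rose by 1.02 ± 0.14 on the log2 scale (adjusted p = 1.15e-04), IFITM1 by 0.96 ± 0.17 and OASL by 0.74 ± 0.15. IFITM1 is uncertain because it shares sequence with IFITM2 and IFITM3. The list ranked higher than other genes (camera adjusted p = 0.00826), but adjusted p = 0.970 with an estimated correlation, 0.396 with fry, 0.498 without replicate 1 and 0.0566 without the block.

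Of the 25 tested genes for sensing of double-stranded RNA and DNA, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.743 with an estimated correlation, 0.153 with fry, 0.165 without replicate 1 and 0.0648 without the block). The 6 were TREX1, an exonuclease that removes cytosolic DNA (14.4 ± 4.69 to 34.6 ± 14.9 CPM; log2 fold change 1.24 ± 0.10, adjusted p = 2.75e-06), the DNA sensing adaptor STING1 (0.45 ± 0.10), the toll-like receptor adaptor MYD88 (0.44 ± 0.07), OAS3, ADAR and IRF3. In the list of JAK-STAT receptors and regulators, 10 of 36 rose and 3 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.361). CSF2RB, the shared beta chain of the GM-CSF receptor, rose by 0.94 ± 0.11 (adjusted p = 3.71e-04), the feedback inhibitor SOCS3 by 0.87 ± 0.16 and JAK3 by 0.62 ± 0.10, while IFNAR2 and JAK2 were among those that fell.

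Among inflammatory cytokines and NF-kB targets the changes past the test were upward. Of 34 tested members 18 rose, 0 fell and 16 did not pass, with the same 18 and 0 adjusted over the list alone and a median log2 fold change of 0.34. Donors differed, with median log2 ratios of 0.043, 0.474, 0.462, 0.113 and 0.425 in replicates 1, 4, 5, 6 and 8. The hyaluronan-binding protein gene TNFAIP6 rose to 42.3 ± 19.6 CPM in the knockout (1.09 ± 0.11, adjusted p = 4.28e-05). INHBA, which encodes the activin A chain, rose from 13.7 ± 10.1 to 28.7 ± 23.3 CPM (0.99 ± 0.15, adjusted p = 8.5e-04). The NF-kB inhibitor NFKBIA rose from 106 ± 63.8 to 158 ± 93.5 CPM (0.63 ± 0.16, adjusted p = 0.0297; 0.122 and 0.120 without replicates 4 and 5, and 0.0599 with no filter). Camera gave adjusted p = 1.27e-06 for the list, and adjusted p = 0.743 with an estimated correlation, and fry did not pass (adjusted p = 0.0618). The list of co-stimulatory and inhibitory ligands also held receptors and the enzyme gene IDO1. Of its 27 tested members 12 rose and 3 fell (HAVCR2, TNFSF10 and TNFSF13B), or 14 and 3 adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.743 with an estimated correlation, 0.0618 with fry and 0.0727 without the block). Examples of those that rose were IDO1, the inhibitory receptor LILRB3 (0.69 ± 0.08, uncertain because of close LILR copies) and the receptor CD40 (0.59 ± 0.09, adjusted p = 6.93e-04). Chemokines and their receptors moved in both directions, with 6 of 23 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.111; 0.01 without replicate 4 and 0.0328 without 6). CCL3 rose by 0.93 ± 0.20 (adjusted p = 0.02) and CCL4 by 0.85 ± 0.18 (adjusted p = 0.00355), both uncertain because of near-identical gene copies. CCL2, the monocyte attractant, fell by 0.48 ± 0.14 (adjusted p = 0.0496). CCL3 was lost without replicate 4, 5, 6 or 8 (0.0794, 0.0746, 0.068 and 0.0548) and CCL2 without 4, 5 or 6 (0.164, 0.0772 and 0.130). CCL2 was also lost with DESeq2 size factors (0.0501), total counts (0.0508), no filter (0.0738), the older edgeR test (0.0605) and the GC content and length correction (0.131). CCL1, CXCL8 and CCR1 also rose, and CCL7 and CCR2, the receptor of CCL2, fell (CCR2 log2 fold change -1.43 ± 0.24, adjusted p = 0.00217, lower in 4 of 5 donors).

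**Figure D4:**
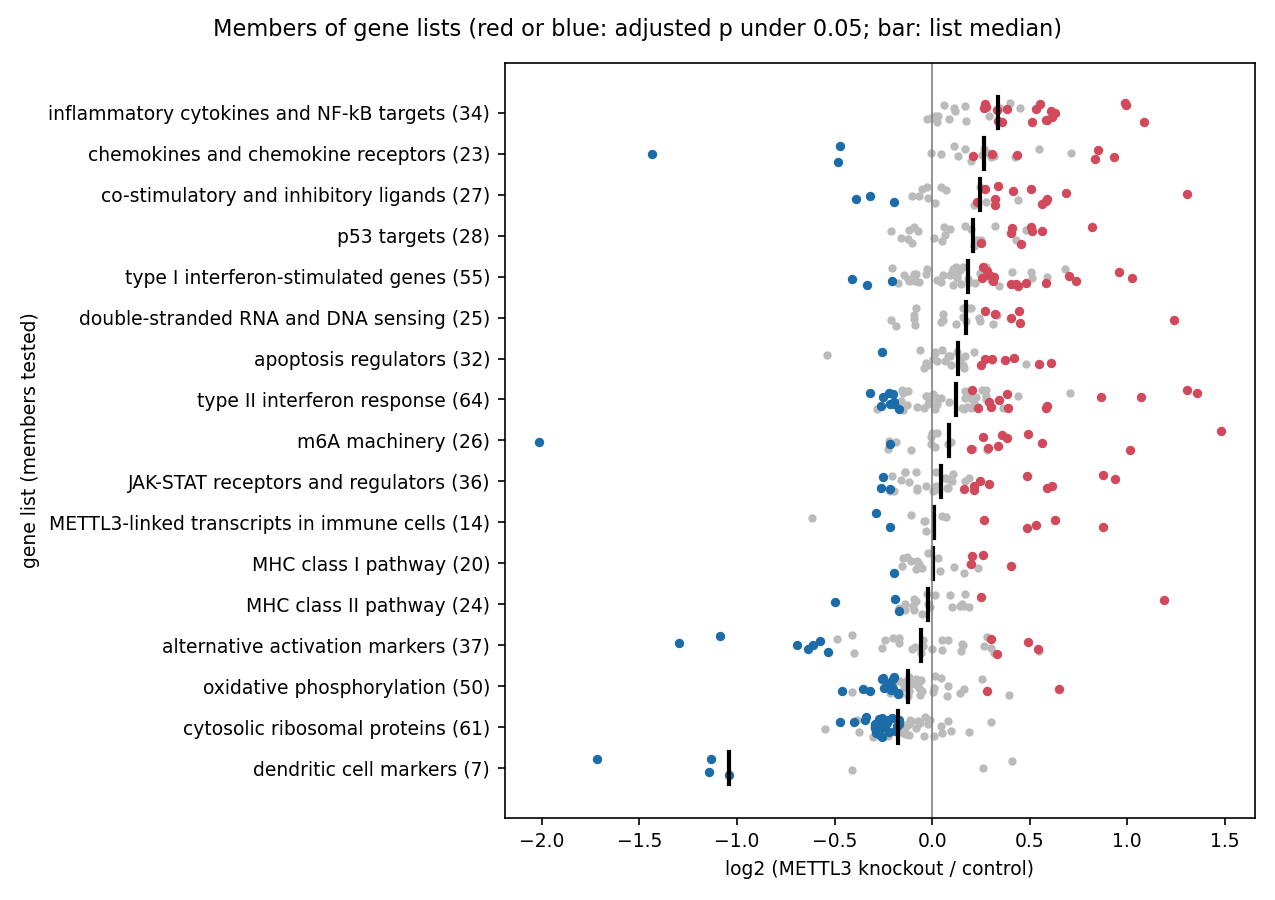
Log2 fold change of knockout over control (x axis) of each tested member of 17 gene lists (y axis, number tested in brackets), red or blue where adjusted p was under 0.05, grey elsewhere, with a black bar at the list median. The inflammatory and NF-kB list has 18 red and 0 blue points, the ribosomal protein list 0 red and 24 blue points.

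Antigen presentation genes changed little as groups. In the MHC class I pathway 4 of 20 members rose (among them TAP2, NLRC5 and TAPBP) and PSME2 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.848). With the GC content and length correction 2 rose and 4 fell. The peptide transporter gene TAP2 had a log2 fold change of 0.41 ± 0.11 (adjusted p = 0.0106; 0.0742 without replicate 5) and the proteasome activator PSME2 one of -0.20 ± 0.06 (adjusted p = 0.0191; 0.0646 and 0.0625 without replicates 1 and 4). In the MHC class II pathway 2 of 24 rose (HLA-DOB and CTSS) and 3 fell (HLA-DOA, IFI30 and CIITA), or 0 and 1 adjusted over the list alone (camera adjusted p = 0.825). HLA genes are uncertain, since donors' alleles differ from the reference. Among alternative activation markers 4 of 37 rose (CD209, ALOX5, IL4R and MRC1) and 7 fell (FN1, STAB1, IL10, TGFBI, MERTK, GAS6 and SELENOP), the same adjusted over the list alone. The matrix protein TGFBI went from 808 ± 486 to 502 ± 234 CPM (-0.64 ± 0.08, adjusted p = 5.15e-05). That list did not pass (camera adjusted p = 0.0991), but did without replicate 5 or 8 (0.0207 and 0.0429). In the list of transcripts linked to METTL3 in immune cells 5 of 14 rose and 2 fell (among them TLR4), the same adjusted over the list alone (camera adjusted p = 0.521). SOCS3, NFKBIA, CISH, RIPK2 and IRAK3, an inhibitor of toll-like receptor signalling (0.53 ± 0.08, adjusted p = 3.79e-04), were the 5.

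Macrophage markers were abundant in both groups. LYZ, lysozyme, stood at 7070 ± 1942 CPM in control and 7724 ± 1648 CPM in knockout libraries (log2 fold change 0.15 ± 0.09, adjusted p = 0.228). Of 15 macrophage markers 2 rose (MRC1 and SPI1) and AIF1 fell, the same adjusted over the list alone (camera adjusted p = 0.664). The GC content and length correction gave 2 higher and 3 lower. Of 9 monocyte markers 1 fell, the same adjusted over the list alone, and MNDA was at -0.14 ± 0.09 (adjusted p = 0.305; list 0.578). Dendritic cell markers ranked lower than other genes (camera adjusted p = 0.0349; adjusted p = 0.743 with an estimated correlation, 0.0618 with fry, 0.0644 and 0.0839 without replicates 1 and 4). The lipid antigen presenting molecules CD1A, CD1B, CD1C and CD1E fell, by 1.72, 1.04, 1.14 and 1.14 on the log2 scale, from control means of 2.67, 4.15, 5.10 and 2.24 CPM. These were 4 of 7 tested markers, also adjusted over the list alone. CLEC10A was at -0.41 ± 0.22 (adjusted p = 0.225), or -0.72 without replicate 8 (adjusted p = 7.42e-04), and LAMP3 and BATF3 at 0.41 ± 0.19 and 0.26 ± 0.31 did not pass. Of markers of other blood cells, 4 for T cells, 2 for NK cells, 3 for platelets and 2 for mast cells were tested, and 0 for B cells and 0 for erythroid cells. Those that rose were IL7R, GZMB, CLEC1B and GP1BA, the same adjusted over the list alone, except that 1 NK cell marker was then also lower. Among the markers of highest CPM, CD4, which macrophages also express, was at 0.04 ± 0.06, NCAM1 at -0.44 ± 0.20 and CPA3 at -0.51 ± 0.26, and none of these passed. Of 6 neutrophil markers 0 passed in edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, also 0 adjusted over the list alone (camera adjusted p = 0.676), with CSF3R at -0.10 ± 0.06. Of 6 fibroblast and endothelial markers KDR and COL1A1 rose and VWF and TIE1 fell, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.782), with PECAM1 at 0.16 ± 0.07 (adjusted p = 0.117).

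Transcripts of cytosolic ribosomal proteins were lower, with 24 of 61 tested members down and 0 up, or 25 and 0 adjusted over the list alone, and a median log2 fold change of -0.18 (camera adjusted p = 1.86e-06; adjusted p = 0.743 with an estimated correlation; fry adjusted p = 0.0253). RPL24, the member named by rule, fell from 17.5 ± 3.29 to 12.7 ± 3.39 CPM (-0.47 ± 0.10, adjusted p = 0.0034). Counts of these genes are uncertain because of their many pseudogenes. In oxidative phosphorylation 14 of 50 members fell and 2 rose (UQCRFS1 and UQCR10), or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00563; adjusted p = 0.743 with an estimated correlation, 0.0805 with fry and 0.0618 without replicate 1). UQCRFS1, a complex III subunit with pseudogene copies, was the largest change, at 0.65 ± 0.10. Of 13 mitochondrially encoded transcripts MT-ND1 rose (0.18 ± 0.06, adjusted p = 0.0415; 0.188, 0.119 and 0.0563 without replicates 5, 6 and 8, and 0.0534 with non-robust dispersions), with 0 adjusted over the list alone (camera adjusted p = 0.664). Among p53 targets 8 of 28 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.743 with an estimated correlation and 0.0618 with fry). The stress cytokine GDF15 was at 0.56 ± 0.15 (0.0691 without replicate 5). Among apoptosis regulators 7 of 32 rose and APAF1 fell, the same adjusted over the list alone (camera adjusted p = 0.0495; adjusted p = 0.743 with an estimated correlation and 0.0618 with fry). The named member BIRC3, an inhibitor of cell death, was at 0.61 ± 0.18 (adjusted p = 0.0473) and was lost without replicate 1, 4, 5 or 6 (0.0572, 0.156, 0.110 and 0.105). BIRC3 was also lost with upper-quartile scaling (0.0631), total counts (0.0546), no filter (0.0821), DESeq2 (0.0545), the older edgeR test (0.0684) and the GC content and length correction (0.0689). The p53 list was lost without replicate 1, 4 or 5 (0.0618, 0.091 and 0.0853) and without the block (0.0689), and the apoptosis list without 1 or 5 (0.128 and 0.0853) and without the block (0.0727).

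The remaining lists did not pass camera. In phagocytic receptors and lysosome 10 of 43 rose and 4 fell (CD36, ATP6V1H, NPC2 and FCGR3A), or 13 and 4 adjusted over the list alone (adjusted p = 0.157; 0.0149 without replicate 4). The collagen-degrading cathepsin CTSK went from 299 ± 133 to 636 ± 214 CPM (1.12 ± 0.10, adjusted p = 3.41e-05). For NADPH oxidase the numbers were 3 up (NCF4, CYBB and HVCN1) and NCF1, uncertain because of its pseudogenes, down of 8, the same adjusted over the list alone (0.521). NCF4 was at 0.30 ± 0.08 (0.065 without replicate 5). For inflammasome and pyroptosis genes they were 4 up (NLRP12, NINJ1, GSDMD and IL18) and 2 down (NAIP and CASP4) of 18, the same adjusted over the list alone (0.664). NLRP12 was at 0.50 ± 0.13 (0.0631 without replicate 5). Of 29 immediate early genes FOSL2 and IER5 rose and FOS, KLF6 and ATF3 (-0.31 ± 0.07) fell, or 0 and 3 adjusted over the list alone (0.782). Unfolded protein and integrated stress response genes split 5 up and 4 down of 31, the same adjusted over the list alone (0.995), or 4 up and 5 down with the GC content and length correction. The member named by rule was the cystine transporter SLC7A11, at 0.84 ± 0.22 (adjusted p = 0.0338; 0.101, 0.127 and 0.0853 without replicates 1, 5 and 6, 0.0665 with no filter and 0.0614 with the GC content and length correction). In the heat shock list DNAJB1 rose (0.22 ± 0.06; 0.0662 and 0.0927 without replicates 1 and 5) and HSP90AA1 fell of 13, the same adjusted over the list alone (0.990). Cholesterol biosynthesis had 5 up and 3 down of 24, or 6 and 3 adjusted over the list alone (0.664), with the sterol dehydrogenase NSDHL at 0.37 ± 0.06. Cholesterol efflux and lipid droplet genes had 5 up and 3 down of 19, or 5 and 6 adjusted over the list alone (0.782). Their balance turned to 3 up and 4 down with the GC content and length correction. The fatty acid receptor CD36 went from 280 ± 105 to 180 ± 68.9 CPM (-0.64 ± 0.08, adjusted p = 6.39e-05). In glycolysis CA12 and EGLN3 rose and BNIP3, PGK1, ENO1 and LDHA fell of 29, the same adjusted over the list alone (0.676). PGK1 was at -0.18 ± 0.06 (0.0771, 0.0547 and 0.103 without replicates 1, 4 and 5) and uncertain because of pseudogenes.

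Zinc finger, histone, cell cycle, splicing and mRNA decay genes did not pass as lists either. Of 417 ZNF zinc finger genes 27 rose and 24 fell, or 20 and 11 adjusted over the list alone (camera adjusted p = 0.676), the named member being ZNF316 (0.83 ± 0.10). Of 7 tested histone genes 0 passed in edgeR, also adjusted over the list alone (0.959), with 1 at an unadjusted p under 0.05 and 0 past DESeq2 or limma-voom. In S phase FEN1 (0.44 ± 0.09), CHAF1A and MCM3 rose of 27, the same adjusted over the list alone (0.974). In G2 and M phase 0 of 26 passed in edgeR, also adjusted over the list alone (0.825), with 3 at an unadjusted p under 0.05, 1 past DESeq2 and 1 past limma-voom. Among RNA splicing factors SRSF4 rose and HNRNPH1, SRSF6, HNRNPD and HNRNPL fell of 36, or 1 and 2 adjusted over the list alone (0.171), with HNRNPH1 at -0.46 ± 0.06 (adjusted p = 4.91e-05). In mRNA decay 8 rose and 5 fell of 38, the same adjusted over the list alone (0.539). ZC3H12A, an RNase that degrades cytokine transcripts, was at 0.61 ± 0.11 (adjusted p = 0.00107). Median and mean log2 fold change or camera's direction differed in sign for the MHC class II, immediate early, unfolded protein response, cholesterol efflux, glycolysis and G2 and M phase lists, none of which passed.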

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

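In this part no explanation was tested, and the test for distant libraries was chosen before the data were examined. Within each group of 5 libraries, the highest and lowest value of each gene named in the text by the rule and of the library totals was compared with the nearest of the others by Dixon's test. Of 160 groups of values 13 held a library past the bound. Of these, 7 were in replicate 4, 5 in replicate 8 and 1 in replicate 1, and 11 were the highest of their group. Chance gives about 8 if values are normal and groups independent. CPM was not log-transformed here and the knockout and control groups share donors, so 8 is only a rough guide. No biological explanation was tested, since the labels give no property of a donor that was used here.

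In replicate 4 the knockout library stood apart for FN1 at 11870 CPM (others 476 to 2576), H2AJ at 17.82 CPM (4.191 to 8.08), IRAK3 at 58.78 CPM (26.67 to 30.82), and METTL14 at 19.39 CPM (29.23 to 32.28). Its 10 most abundant genes took 11.8% of counts (10.77 to 11.03). FEN1 stood apart in both libraries of that donor, at 66.99 CPM in the knockout (16.77 to 22.99) and 43.9 CPM in the control (10.74 to 17.62).

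In replicate 8 ABCG2 was the highest in both libraries, at 22.17 CPM in the knockout (2.233 to 7.068) and 43.76 CPM in the control (5.746 to 15.55). SCIN was the highest in its knockout library at 84.87 CPM (3.202 to 24.5) and PGK1 in its control library at 841.3 CPM (758.5 to 779.7). The summed markers of lymphocytes and platelets reached 17.68 CPM in its control library (1.56 to 4.766). The knockout library of replicate 1 had the lowest total, 15362479 counts (15.36 on the scale of 1e6 counts, where the others were at 15.66 to 15.75). Where a donor stood apart in both libraries, as for FEN1 and ABCG2, the test within donors compared these libraries with each other.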

How the results depend on the processing

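The correction for GC content and coding length was chosen after the result was seen; the other alternatives were planned. METTL3 was lower in all 18 alternatives, at -2.11 to -1.93 (highest adjusted p 7.33e-05). The count of 2873 genes was within 1.5 times of itself under other scaling, filters and tests and with the GC correction, at 2335 (DESeq2) to 3210, and no call changed sign in any alternative. The genes called were not all the same. Of the 3210 with the GC correction 2559 were among the 2873, and of the 2335 with DESeq2 2307 were.

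Without the replicate block 10 genes passed (9 higher, 1 lower), as donor differences then enter the error by construction. With 1 surrogate variable in its place 208 passed (149 and 59). Against a fold of 1.2 the number was 538 (373 and 165), since that test asks for a larger change by construction. Leaving out a replicate gave 1696 to 2491 genes, 961 to 1397 higher and 735 to 1100 lower, with the fewest without replicate 5. Fewer libraries lower the count by construction, but why replicate 5 lowered it the most was not tested.

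Of the 37 lists 10 passed camera. With an estimated correlation 0 passed, with fry 2, without the block 5, and without a replicate 3 to 12, the fewest without replicate 1. The type I interferon list (adjusted p = 0.00826) was at 0.970 with an estimated correlation, 0.396 with fry, 0.0566 without the block and 1.87e-06 to 0.498 when leaving out a replicate. The type II list (0.111) ran from 0.00308 to 0.498 when leaving out a replicate. For these lists the cause was not tested.

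With the GC correction the balance of calls turned for MHC class I (4 higher and 1 lower to 2 and 4), the unfolded protein response (5 and 4 to 4 and 5), cholesterol efflux (5 and 3 to 3 and 4) and macrophage markers (2 and 1 to 2 and 3). Fewer members rose in the NF-kB list (14, with 0 lower), and more fell in alternative activation (11), glycolysis (9), oxidative phosphorylation (20) and ribosomal proteins (32). Camera was not run with that correction.

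Of the 75 genes taken by the naming rule 60 passed. Of these 43 passed in every leave-one-out fit and 17 did not in at least 1. The call was lost for 56 without the block, 47 with the surrogate variable, 22 against the fold of 1.2, and 6 under at least 1 of the 10 other alternatives. Of the genes that did not pass, 6 passed in at least 1 alternative. IRF1 (0.01) reversed to -0.0023, -0.0593 and -0.0063 without replicates 1, 5 and 6 and to -0.0388 with the GC correction, and CD4 (0.04) to -0.0219 with that correction, all far from the threshold and at most 0.0981 for IRF1 in a leave-one-out fit; the cause was not tested. On simulated counts the test recovered 26.0% of genes at a fold of 1.2 and 98.0% at 1.5. These were genes with a mean of at least 5 CPM, and recovery below that level was not simulated. Only 200 genes were changed there, against 2873 called in the real counts. The adjustment of p values depends on how many genes change, so recovery at small folds may differ in the real counts.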

Other observations

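The test for RNA of lymphocytes or platelets, the GC correction and the values of the last paragraph but one were chosen after the result was seen. Across 11261 genes with an annotated principal transcript, the log2 fold change fell with the number of exon junctions per kilobase (Spearman rho -0.183, bootstrap interval -0.202 to -0.164 over 1000 draws). Genes are not independent replicates, but the sign was the same in each donor (-0.136, -0.122, -0.132, -0.166 and -0.126). Of the 2253 genes with the fewest junctions 21.0% rose and 6.92% fell, and of the 2252 with the most 7.33% rose and 17.1% fell. Of 193 single-exon genes 45 rose and 9 fell.

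Methylation by METTL3 is known to fall mainly in long exons, since junction complexes keep it from nearby sequence, and it shortens the life of transcripts. A candidate explanation of the relation is that transcripts with long exons lose methylation and become more abundant. The rho of -0.183 only restates the relation, and as methylation and decay were not measured here it cannot be told apart from other causes linked to exons. A bias by GC content or length as the cause of the junction relation is argued against by the partial rho of -0.267 given GC content, both lengths and CPM. GC content had a relation of its own with the fold change, with rho 0.223 and partial rho 0.246 given junction density, both lengths and CPM. A GC bias in the fold changes is thus not excluded. Genomic DNA in the knockout libraries, which would matter little for abundant genes, is argued against by the rho of -0.23 in the 2253 genes of highest CPM.

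Ribosomal protein transcripts have many junctions and might be lower for that reason or for technical ones. Their median of -0.18 lay at percentile 0.0 of 10000 random lists matched on junction density and GC content, whose median was -0.0087. Junction density and GC content alone are thereby argued against. The lists were not matched on the longest coding exon, whose rho with the fold change was 0.269, so exon architecture as a whole stays open. Members of random lists were drawn independently, so the percentile takes no account of genes that move together. The GC and length correction left a median of -0.206 (bootstrap SE 0.025), which argues against those trends. Members with fewer processed pseudogenes than the median still had -0.151 (SE 0.028), which argues against shared reads as the whole cause. Those with as many or more had -0.221 (rho of pseudogene number with fold change -0.159), so shared reads as a part of it, and a biological cause, stay open.

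The inflammatory and NF-kB list and the type I interferon list lay at percentile 100.0 and at percentile 100.0 of lists matched in the same way. Their medians were 0.336 and 0.184, against 0.0232 and -0.0037 for matched lists. Junction density and GC content alone are therefore unlikely to give either, while the longest coding exon was not matched. These percentiles also take no account of genes that move together. RNA from lymphocytes or platelets is argued against for the NF-kB list, since the summed level of 12 of their markers was at most 6.83 CPM in a knockout library. It rose in 3 of 5 donors, but in replicates 4 and 8, where it fell, the list's median was 0.474 and 0.425. In replicates 1, 5 and 6, where it rose, the list's median was 0.043, 0.462 and 0.113. The markers GP1BA and CLEC1B rose. PPBP, abundant in platelets, stood at 4.73 and 3.49 CPM in control and knockout. That control mean depends on replicate 8, whose control library had 17.68 CPM of the summed markers, PPBP included (others 1.56 to 4.766). The 2 means of PPBP therefore do not decide about platelet RNA. Whether an effect of METTL3 loss on the genes of either list may be direct was not tested, and the type I list was lost without replicate 1 (adjusted p = 0.498).

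Not all junction-poor lists followed the relation. The ZNF genes had a median of -0.021 where matched lists had 0.0461, and the immediate early genes 0.003 where matched lists had 0.172. The rho with the longest coding exon was 0.269, whereas that with the longest internal exon was 0.097 (partial 0.087, and 0.023 in replicate 8) and that with the length of the 3' UTR was -0.011. The rho with GC content differed between donors, at -0.017, 0.373, 0.327, -0.063 and 0.077 in replicates 1, 4, 5, 6 and 8. Within 1 megabase of METTL3, 15 genes were tested, of which RNASE6, NDRG2 and ARHGEF40 rose and 0 fell, with NDRG2 at 1.04 ± 0.10. The largest fold change of all genes tested was that of MS4A6E, which rose by 3.57 ± 0.48 from 0.493 CPM, with its mean under the CPM floor of the naming rule.

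The count of 2873 genes was compared with other splits of the 10 libraries into 5 and 5. Since the libraries are paired by donor, the comparison is with the 16 splits that part every pair, of which 1, the real one, called as many and the highest of the others called 2. These 16 are too few for a share under 0.05, since it cannot go under 0.0625. The other splits drawn, of 100 in all, parted only some of the pairs. With donor as a block, only the pairs that a split parts bear on its contrast. These splits called at most 564 genes, in a split that parted 3 pairs, with a median of 0.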
